A study of Mus musculus with 41 samples.

How the data were processed

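RNA from 41 mouse melanomas was measured with Affymetrix Mouse Genome 430 2.0 arrays as biotin-labelled cRNA, per the labels' protocols. The deposited table holds 1 value per probe set and array, in intensity on a linear scale. The submitters' processing notes name both RMA and MAS5, without a version and without saying which of them made the table. The authors' values have nearly the same distribution in every array and none is missing. No detection calls and no genome build were given, and arrays have no sequencing depth.

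The values were turned into log2(value + 16) and quantile normalised between arrays, so the unit used throughout is log2 intensity computed from the deposited intensity. Of 45101 probe sets, 34958 named 1 gene, 932 named several and 9211 named none, and only the first kind was used. For a gene with several probe sets the one with the highest mean over all arrays was kept, which gave 18194 genes. A gene was tested when its probe set lay above the 40th percentile of its array in at least 3 arrays, which left 14318. Of the probe sets with 1 gene, 34754 had an Entrez identifier in the RefSeq table and 0 symbols were updated.

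Groups were the days off doxycycline in the labels, with days 63 to 163 pooled, as single late days had too few tumours. Days 16 and 29 had 1 tumour each and entered no comparison. One limma fit (limma 3.58.1 in R 4.3.3) with a mean per group over all 41 tumours gave moderated tests with 32 residual and 2.58 prior degrees of freedom, so each comparison borrowed its spread from all groups. The 8 comparisons were days 1, 2, 3, 6, 9 and the late tumours against day 0, the late tumours against the mean of the group means of days 6 and 9, and day 6 against day 1. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p values of genes are limma's. The groups, comparisons, gene lists, filter and the rule for naming genes were fixed before the data were examined.

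The rule named, in 6 of the comparisons, the 6 largest rises and 6 largest falls among called genes, up to 4 members of each list with the lowest p, and a fixed set of MAPK, melanocyte and receptor genes. The text gives some of these. At days 1 and 2 the rule covers only the fixed set, and Apoe, Lyz2, C1qb, Ccl5, Cfb, Spred3 and Dusp4 were given there after their values had been seen.

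Altogether 34 gene lists, of signalling and metabolic programmes and of cell types, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Members called are counted over all genes and adjusted over the list alone. Some genes are in more than 1 list, and tumour cells also express some cell type genes. The 10 genes of the MAPK activity score all lie within the MAPK output list. A list score per tumour, the mean log2 value over the tested members, was compared between groups by a two-sided exact permutation test of the difference of means, adjusted over the 34 lists of a comparison. For the late tumours against days 6 and 9 that test pooled the 7 earlier tumours. The p values given with scores are from this test, and those given with camera medians are camera's.

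The pipeline was tested on simulated data with 200 genes changed at each fold given here and the MAPK output genes lowered 2-fold. The simulated noise was independent between genes and held no effect of spike-in set or RNA quality, so these rates need not hold for the real arrays. For day 9 against day 0 it recovered 49% of the genes changed 1.5-fold, 78% of those changed 2-fold and 95.5% of those changed 4-fold. For the late tumours against day 0 it recovered 62%, 90% and 99.5% at the same folds. Of the genes called, 3.76% and 5.27% were false in those comparisons.

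Alternatives set in advance were another array scaling, pseudocounts of 1 and 64, no filter and one at the 60th percentile, other ways to treat several probe sets, robust limma with a trend, array weights, a fit of the compared groups alone, a 2-fold limit, each tumour left out in turn, number ranges of the titles, other pooling of days, and a slope per day. Added after the data had been seen were unnormalised arrays, no pseudocount, the Gapdh 3′ to 5′ gap as a covariate or a limit, the spike-in set as a block or a subset, and day 2 in place of day 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No paired analysis was possible because replicate numbers only follow the order of deposit.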

Results

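Gene expression was measured in 41 melanomas of mice in which a doxycycline-inducible BRAF transgene drives tumour growth (the iBIP model), on Affymetrix Mouse Genome 430 2.0 arrays. Doxycycline was removed from the drinking water, which switches the transgene off, and tumours were collected at stated numbers of days off the drug. Tumours still on the drug, called day 0, numbered 4. After withdrawal there were 7 tumours at day 1, 5 at day 2, 6 at day 3, 4 at day 6, 3 at day 9, 1 at day 16, 1 at day 29 and 10 between days 63 and 163. These last 10, from days 63, 77, 90, 121, 136 and 163, are called the late tumours. The labels do not say whether a late tumour was a remnant or had regrown, nor that each tumour came from a separate mouse. The number of arrays per group limits the precision of every difference below.

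Of 45101 probe sets, 34958 named exactly 1 gene, which gave 18194 genes, and 14318 of them passed the filter on low values. Values are log2 intensities, differences are log2 fold changes with their standard error (SE), and a list score is the mean log2 value over the genes of a list in 1 tumour. The pseudocount shrinks the fold changes of weakly expressed genes.

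Some facts about the arrays follow the groups. Every tumour of days 1, 2, 3 and 6 has a 4-digit number starting with 1 in its title, and none of day 0, day 9 or later has. Spike-in controls, bioD added at hybridization and dap added before labelling, put the arrays into 3 sets. Arrays with a log2 bioD value below 12 formed set 1. The rest formed set 2 where dap was below 9.4 and set 3 otherwise. Dap reached 9.24 in set 2 and started at 9.59 in set 3, a narrow boundary, so the sets need not be separate batches. Set 1 holds all tumours of days 2, 3 and 6 and 1 of day 1, set 2 holds the other 6 of day 1 and 8 late tumours, and set 3 holds day 0, day 9, day 16, day 29 and 2 late tumours. The gap between the 3′ and 5′ Gapdh control probe sets, which widens when RNA is degraded, averaged 0.48 ± 0.11 (SD, n = 4) at day 0, -0.09 ± 0.07 (n = 4) at day 6, 1.22 ± 1.01 (n = 3) at day 9 and 2.68 ± 1.44 (n = 10) in the late tumours. It exceeded 2 in 1 tumour of day 9 and in 8 late tumours. Both the spike-in sets and the limit of 2 were chosen after the data had been seen.

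**Figure D1:**
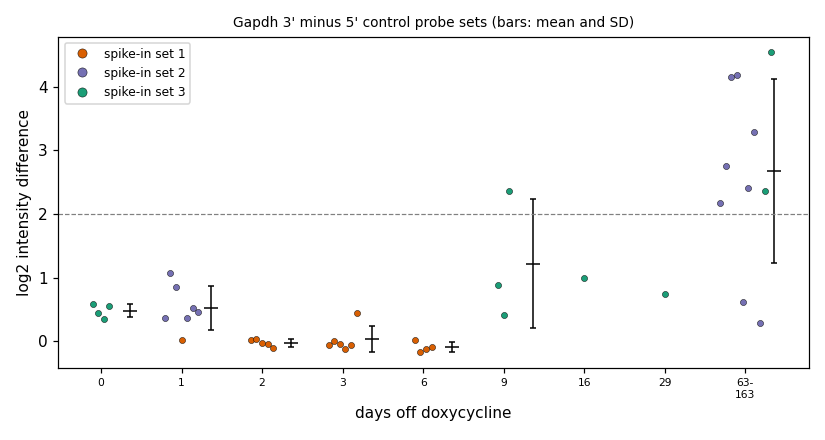
Gap between the 3′ and 5′ Gapdh control probe sets (log2) for each of the 41 tumours by days off doxycycline, with group means and SD, and a dashed line at 2. The late tumours averaged 2.68 and day 0 averaged 0.48.

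The first question was whether the transcriptional output of the MAPK pathway, which BRAF drives, fell after withdrawal. Dusp6, a phosphatase gene induced by ERK, averaged 11.08 ± 0.21 (SD, n = 4) at day 0, 10.36 ± 0.39 (n = 7) at day 1, 9.93 ± 0.33 (n = 4) at day 6, 9.86 ± 0.70 (n = 3) at day 9 and 9.64 ± 0.22 (n = 10) in the late tumours. Etv4, an ETS transcription factor gene downstream of ERK, went from 8.22 ± 0.16 at day 0 to 6.76 ± 0.15 in the late tumours. Ccnd1, which encodes cyclin D1, went from 12.55 ± 0.26 to 10.39 ± 0.39 between the same groups. A score of 10 MAPK target genes averaged 9.09 ± 0.20 (SD, n = 4) at day 0, 8.49 ± 0.25 (n = 7) at day 1, 8.30 ± 0.30 (n = 5) at day 2, 8.08 ± 0.22 (n = 6) at day 3, 8.03 ± 0.22 (n = 4) at day 6, 8.03 ± 0.51 (n = 3) at day 9 and 7.83 ± 0.18 (n = 10) in the late tumours. Day 3 was lower than day 0 by an exact permutation test of 210 splits (difference -1.01 ± 0.13 SE, adjusted p = 0.0162 over 34 lists), and so were the late tumours (difference -1.26 ± 0.11, adjusted p = 0.00679). At day 9 the exact p of 0.0286 is the smallest that 35 splits allow, and its adjusted value was 0.243. The mouse Braf probe set of highest intensity rose by 0.59 ± 0.10 in the late tumours (adjusted p = 1.71e-05), another fell by 1.61 there and was below day 0 at every time, and the mean over all Braf probe sets gave -0.02. Which of them, if any, detects the transgene is not known. Cdkn2a and Tyr did not pass the filter.

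**Figure D2:**
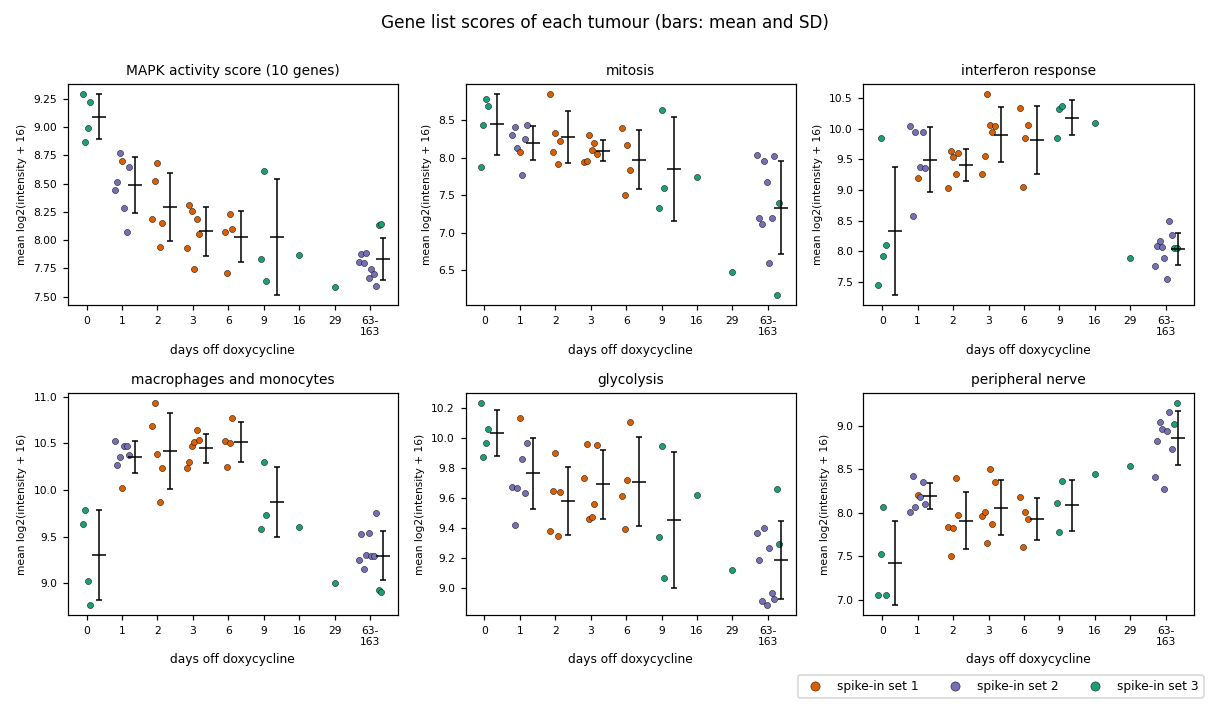
Scores of 6 gene lists (mean log2 intensity) for each tumour by days off doxycycline, coloured by spike-in set, with group means and SD. The MAPK activity score averaged 9.09 at day 0 and 7.83 in the late tumours, and the interferon response score averaged 10.18 at day 9 and 8.04 in the late tumours.

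At day 1, the earliest time, macrophage genes were higher than at day 0 in 14 of 30 members, 19 over the list alone, T and NK cell genes in 22 of 26, 24 over the list alone, and complement genes in 8 of 15 with 1 lower, 9 and 1 over the list alone. MAPK output genes were lower in 10 of 28, 13 over the list alone. Apoe rose by 2.70 ± 0.35 (SE, adjusted p = 1.9e-05), Lyz2 by 1.93 ± 0.27, Ccl5 by 2.89 ± 0.54 and complement factor B, Cfb, by 2.20 ± 0.31. Spred3, an ERK pathway inhibitor that is itself induced by the pathway, fell by 1.13 ± 0.20 (adjusted p = 0.000403), Dusp6 fell by 0.72 ± 0.22 and Spry4 fell by 0.63 ± 0.19. The Dusp6 and Spry4 calls (adjusted p = 0.0259 and 0.0256) ended without day 0 replicate 1 or 4 or day 1 replicate 5, that of Spry4 also without day 1 replicate 6 (0.0515 to 0.129), and Spry4 was at -0.33 (adjusted p = 0.0534) as a mean of its probe sets. The macrophage score was higher by 1.05 ± 0.25 (adjusted exact p = 0.0258) and the MAPK activity score lower (-0.60 ± 0.14, adjusted exact p = 0.0258). Both calls ended without day 0 replicate 3 or 4 (0.0567 each) or day 1 replicate 7 (0.054 and 0.0648), and the MAPK call also without day 0 replicate 1 (0.0515). The complement score was higher by 1.18 ± 0.23 (adjusted exact p = 0.0258), a call that ended without the same 3 tumours (0.054 to 0.0567). The T and NK cell score was higher by 1.36 ± 0.28 (adjusted exact p = 0.0386), a call that ended (0.0567 to 0.0944) without day 0 replicate 3 or 4 or day 1 replicate 3, 5, 6 or 7. In limma, 1084 genes rose and 895 fell, against 889 in all without day 0 replicate 4. Arrays centred on their medians put 67.6% of the changed genes higher and the spike-in block 67.9%, against 54.8%, while every probe set tested gave 46.3%.

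At day 2 macrophage genes were higher in 14 of 30 members, 20 over the list alone, and MAPK output genes lower in 14 of 28, 16 over the list alone, while no list score passed the exact test after adjustment (0.0623 and above). Apoe was higher by 2.64 ± 0.37 (SE, adjusted p = 6e-05), C1qb by 1.94 ± 0.36 and Lyz2 by 1.94 ± 0.29. Spred3 fell by 1.61 ± 0.21 (adjusted p = 5.6e-05), Etv4 fell by 0.89 ± 0.18 and Dusp4 fell by 1.75 ± 0.43. The neutrophil list was higher in camera (median 1.53, adjusted p = 3.1e-05; adjusted p = 0.30 with an estimated correlation), with 5 of 19 members higher and 6 when adjusted over the list alone. Day 2 replicate 1 stood apart from the other 4 in the neutrophil score (10.73 against 7.73 to 8.51), and without it the camera median was 0.85 (adjusted p = 0.0046). In limma 965 genes rose and 1196 fell. Leaving out day 0 replicate 4 gave 1178 genes in all and leaving out day 2 replicate 5 gave 1358.

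At day 3 macrophage, interferon and T and NK cell genes were higher and MAPK targets lower. Apoe rose by 2.90 ± 0.36 (SE, adjusted p = 2.69e-06), C1qb by 2.32 ± 0.35, the NK cell receptor gene Klrd1 by 2.74 ± 0.55 and the mast cell protease gene Cpa3 by 2.60 ± 0.62. Interferon-inducible Gbp8 rose by 3.89 ± 0.82 (adjusted p = 0.00114), and the myelin and axon genes Mal and Kcna1 by 3.49 ± 0.60 and 3.48 ± 0.63. Spred3 fell by 1.92 ± 0.20 (adjusted p = 6.92e-07), Etv4 by a log2 change of -1.25 ± 0.17, and the neurofilament gene Nefl by one of -3.57 ± 0.86. In the interferon list 28 of 30 genes rose, 29 adjusted over the list alone (camera median 1.61, adjusted p = 1e-17; adjusted p = 0.13 with an estimated correlation). The day 0 tumours themselves ran from 7.45 to 9.85 in the interferon score. Macrophage genes were higher in 17 of 30 members, 19 over the list alone, and their score by 1.15 ± 0.25 (adjusted exact p = 0.0162). T and NK cell genes were higher in 14 of 26, with 18 over the list alone, and a score difference of 1.15 ± 0.23 (adjusted exact p = 0.0162). MAPK output genes were lower in 17 of 28 and higher in 0, and 19 were lower adjusted over the list alone. Across the array, limma called 1395 genes higher and 1662 lower, and 1633 in all without day 0 replicate 4. Skin keratin Krt10 rose by 4.14 ± 1.31 (adjusted p = 0.0228), a call that reversed in sign to -2.07 with the spike-in set as a block.

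At day 6 the neutrophil and antimicrobial genes S100a9 and Reg3g rose by 4.12 ± 0.98 (SE, adjusted p = 0.00569) and 3.26 ± 0.58 (adjusted p = 0.00051), but were at 1.12 (adjusted p = 0.85) and 2.28 (adjusted p = 0.41) with the spike-in set as a block. Apoe rose by 3.07 ± 0.39, against 2.84 (adjusted p = 0.10) with the block. The mast cell protease genes Cpa3 and Tpsb2 rose by 3.14 ± 0.68 and 2.56 ± 0.44, and were at 3.12 (adjusted p = 0.30) and 2.72 (adjusted p = 0.17) with the block. The list of dendritic and mast cells had 7 of 17 members higher, and 7 higher and 1 lower over the list alone. Complement genes C1s1 and Cfb rose by 2.66 ± 0.42 and 2.53 ± 0.35, against 2.87 (adjusted p = 0.11) and 2.74 (adjusted p = 0.080) with the block. The complement list had 9 of 15 members higher and 1 lower, and 10 and 1 adjusted over the list alone. Its camera call held with an estimated correlation (adjusted p = 0.0499). Among MAPK targets Spred3 fell by 1.98 ± 0.22 (adjusted p = 3.35e-06), Spry2 fell by 1.37 ± 0.21 and Dusp6 fell by 1.15 ± 0.25, and with the block they were at -1.44 (adjusted p = 0.13), -1.48 (adjusted p = 0.092) and -1.28 (adjusted p = 0.23). With 4 tumours against 4 the smallest exact p is 0.0286, and no score passed after adjustment. The MAPK activity score difference was -1.06 ± 0.15 (exact p = 0.0286). In limma 822 genes rose and 925 fell, and the sum was 832 without day 0 replicate 4.

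The days 1 to 6 could not be set against day 0 within 1 number range or spike-in set. A block for the spike-in set ties set 1 to set 2 through a single day 1 tumour. It ties set 2 to set 3, which holds day 0, only through the late tumours, of which 2 are in set 3. That block gave 79 genes at day 2, 134 at day 3 and 70 at day 6. Under that block Apoe, Ccl5 and Cfb kept their calls at day 1 and Lyz2 (0.84, adjusted p = 0.13), Spred3 (-0.63, adjusted p = 0.19), Dusp6 (-0.47) and Spry4 (-0.44) lost theirs, as did every gene named at day 2, where Apoe was at 2.41 (adjusted p = 0.14) and Spred3 at -1.08 (adjusted p = 0.24). At day 3 only Ccl5 (4.98), Nkg7 (4.50) and H2-K1 (1.67) of the genes studied there stayed past 0.05. Apoe (2.68, adjusted p = 0.098) and C1qb (2.59, adjusted p = 0.076) lost their calls there at folds much like those above, and Spred3 (-1.39, adjusted p = 0.11) and Etv4 (-0.91, adjusted p = 0.27) at smaller ones. The camera calls of MAPK output (median -0.76, adjusted p = 2.4e-06), interferon response (1.69, adjusted p = 1.8e-08), T and NK cells (1.86, adjusted p = 1e-09) and macrophages (1.27, adjusted p = 0.00011) held at day 3 under the block. Those calls used the preset correlation and rest on the same few linking tumours, so they cannot settle the part of batch. In the full fit no list of day 3 was called with an estimated correlation (smallest adjusted p = 0.089).

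Day 9 and day 0 share 1 spike-in set and no tumour whose number starts with 1 and has 4 digits. Solute carrier gene Slc9a2 fell by 2.63 ± 0.44 (SE, adjusted p = 0.00103), Spred3 fell by 1.83 ± 0.24 (adjusted p = 0.00011) and Dusp5 fell by 1.72 ± 0.28 (adjusted p = 0.000769). Complement genes C2, Cfb and C1ra rose by 2.37 ± 0.38, 2.25 ± 0.38 and 2.27 ± 0.38, and interferon-inducible Gbp3 and Gbp7 by 2.35 ± 0.45 and 1.77 ± 0.32. In the interferon list 24 of 30 genes rose, 29 adjusted over the list alone (camera adjusted p = 1.7e-24; adjusted p = 0.096 with an estimated correlation), and the score difference of 1.85 ± 0.55 had an exact p of 0.0571. MAPK output genes were lower in 14 of 28 and 20 over the list alone, and this call and that of the MAPK activity score both held with an estimated correlation (adjusted p = 0.0256). The genes of the activity score all lie within the MAPK output list, so these calls are not separate results. Macrophage genes were higher in 4 of 30, 6 over the list alone (camera adjusted p = 0.00044, lost without day 9 replicate 2 at 0.0938; adjusted p = 0.52 with an estimated correlation). In the fit of all 41 tumours limma called 380 genes higher and 273 lower, against 320 and 407 with the mean of a gene's probe sets. With only these 7 tumours limma called 0, and the named genes had adjusted p of 0.176 and above there. The count of 653 became 36 without day 9 replicate 3, 181 without day 0 replicate 4, 278 without day 0 replicate 1, 389 without day 9 replicate 1 and 1236 without day 9 replicate 2. At an unadjusted p under 0.05 the full fit gave 3105. Without all tumours of Gapdh gap over 2, namely day 9 replicate 3 and 8 late tumours, the fit called 24 genes. Among them were Spred3, Apoe, Cfb, C2 and C1ra, while Slc9a2 (-2.35, adjusted p = 0.075), Dusp5 (-1.51, adjusted p = 0.066), Gbp3 (2.26, adjusted p = 0.091) and Gbp7 (1.74, adjusted p = 0.066) lost their calls.

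Day 6 was also compared with day 1, as all of these tumours carry 4-digit numbers starting with 1. The neural crest transcription factor Sox10 fell by 1.46 ± 0.28 (SE, adjusted p = 0.00314), Pdgfa fell by 0.97 ± 0.18 (adjusted p = 0.00282) and Etv4 fell by 0.83 ± 0.17 (adjusted p = 0.00449). Dcun1d1, a neddylation gene, and Net1 rose by 1.38 ± 0.26 (adjusted p = 0.00261) and 1.67 ± 0.33 (adjusted p = 0.00354). MAPK output had 3 of 28 members lower, 6 over the list alone (camera median -0.50, adjusted p = 0.00069; adjusted p = 0.95 with an estimated correlation), and the MAPK activity score differed by -0.46 ± 0.15 (exact p = 0.0182, adjusted 0.206). Keratinocyte and hair follicle genes were higher in camera (median 1.37, adjusted p = 0.0072; adjusted p = 0.95 with an estimated correlation) with 0 of 23 members called in limma. That call ended without day 1 replicate 2 or day 6 replicate 2 (0.051 and 0.154), and the median reversed to -0.16 with the spike-in block. All 4 tumours of day 6 are in set 1 and 6 of 7 of day 1 are in set 2. In limma 239 genes rose and 359 fell (2751 at an unadjusted p under 0.05), but with the spike-in set as a block, or within set 1 alone, limma called 0, where set 1 has 1 tumour of day 1, so that this count says little. Against day 2, which shares set 1, day 6 gave 0 genes, and Sox10 (0.02), Net1 (-0.06) and Dcun1d1 (-0.16) changed sign. The 598 genes became 254, 296, 305 and 368 without day 6 replicates 3, 2, 4 and 1, and 310, 356, 370, 390 and 1165 without day 1 replicates 3, 7, 1, 5 and 4. Arrays centred on their medians put 22.2% of the changed genes higher, and unnormalised arrays 29.9%, against 239 of 598, whereas the mean of a gene's probe sets put 56.6% higher and every probe set tested 61.6%, so the balance of direction is not settled.

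The late tumours were set against day 0 to ask what set tumours long off the drug apart from those still on it. ERK targets fell, Dusp4 by a log2 change of -3.02 ± 0.38 (SE, adjusted p = 1.89e-07), Dusp5 by one of -2.27 ± 0.22 and Spred3 by one of -2.08 ± 0.19 (adjusted p = 2.04e-09). Mmp1a, a collagenase gene, fell by 5.06 ± 0.78 and the chromatin gene Hmga2 fell by 3.96 ± 0.51. Cell division genes dropped too, with Plk1 at -1.87 ± 0.25 and Aurka at -1.46 ± 0.19, and so did the glycolysis genes Pkm at -1.61 ± 0.19 and Hk1 at -1.64 ± 0.21. Some myelin, axon and Schwann cell genes rose, Kcna1 by 5.40 ± 0.58 (adjusted p = 2.24e-08), Mal by 5.27 ± 0.55, Mbp by 4.48 ± 0.77 and the sodium channel gene Scn7a by 4.13 ± 0.46. Others of the peripheral nerve list were not called, namely Mag (0.12), Pllp (0.17), Drp2 (0.32), Egr2 (0.85) and Ncmap (-0.15). Complement genes C1s1 and C2 were higher by 3.12 ± 0.35 and 2.42 ± 0.30. The score of all 15 complement genes differed less, at 8.95 ± 0.30 (SD, n = 10) in the late tumours against 8.44 ± 0.45 (n = 4) at day 0. The melanoma and Schwann lineage cadherin gene Cdh19 rose by 1.94 ± 0.31.

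MAPK output genes were lower in 20 of 28 members and higher in 1, with 20 and 3 adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.27 with an estimated correlation). Mitosis genes were lower in 29 of 32 (camera median -1.15, adjusted p = 1.3e-10; adjusted p = 0.71 with an estimated correlation) and glycolysis genes in 11 of 16, the same counts as over the lists alone. The mitosis score differed by -1.11 ± 0.28 (adjusted exact p = 0.0401), a call that ended (0.0594 to 0.0892) without day 0 replicate 2, 3 or 4 or late replicate 3 or 7. The glycolysis score fell by 0.85 ± 0.11 (adjusted exact p = 0.00679). Adipocyte genes were higher in 8 of 13 and lower in 1, and their score by 1.28 ± 0.20 (adjusted exact p = 0.00679). Peripheral nerve genes were higher in 5 of 10 (camera median 1.01, adjusted p = 0.015; adjusted p = 0.57 with an estimated correlation), and their score by 1.43 ± 0.26 (adjusted exact p = 0.00679). That score was already higher at day 1 than at day 0 (8.19 against 7.43, adjusted exact p = 0.0386), a call that ended without any 1 of 9 tumours (0.054 to 0.106). Skeletal muscle genes were higher in 15 of 21, 17 over the list alone (camera median 1.49, adjusted p = 0.0043; adjusted p = 0.81 with an estimated correlation), but with the Gapdh gap as a covariate the median was 0.09 (adjusted p = 0.75). The interferon score difference of -0.29 ± 0.53 did not pass (exact p = 0.442), and 4 of 30 interferon genes were lower, 2 over the list alone. In limma 3772 genes rose and 2875 fell, a balance that turned with the array settings below.

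Only 2 late tumours had a Gapdh gap of at most 2, and against the 4 of day 0 the smallest exact p is 0.0667, so no score could pass there. Their scores differed from day 0 by -1.46 for MAPK activity, -1.13 for glycolysis, -0.59 for mitosis, 0.48 for adipocytes and 1.08 for peripheral nerve. These tumours, late replicates 5 and 8, had the lowest late scores for adipocytes (7.07 and 7.19) and for the melanocyte lineage (7.27 and 7.37). The gap limit thus cannot separate degraded RNA from a difference in cell content. The adipocyte genes Lpl (1.38, adjusted p = 0.099), Scd1 (1.01, adjusted p = 0.16) and Pparg (0.25, adjusted p = 0.53) lost their calls in those tumours, while Fabp4 was still called (3.93, adjusted p = 0.0046). Of the cell division genes Mki67 (-0.49, adjusted p = 0.27) and Tk1 (-0.78, adjusted p = 0.078) lost theirs, while Plk1 (-1.44, adjusted p = 0.0029) and Aurka (-1.23, adjusted p = 0.00048) were still called.

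Among genes of cell death, Bak1 fell by 1.90 ± 0.27 (adjusted p = 1.54e-06), Birc2 rose by 1.09 ± 0.14 (adjusted p = 2.45e-07), and the pro-apoptotic BIM gene Bcl2l11 fell by 1.75 ± 0.29 (adjusted p = 1.28e-05). Bcl2l11 was at -0.88 (adjusted p = 0.096) without the tumours whose Gapdh gap exceeded 2, at -1.09 and still called as a mean of its probe sets, and at -0.23 on another probe set of similar intensity. Melanocyte regulator Mitf rose by 1.22 ± 0.28 and its target Kit by 1.57 ± 0.40, but with the gap as a covariate they were at 0.49 (adjusted p = 0.23) and 0.98 (adjusted p = 0.14). Pax3, which acts upstream of Mitf, fell by 1.64 ± 0.34, and was at -0.55 (adjusted p = 0.22) with the covariate. Axl, a receptor kinase of undifferentiated melanoma, fell by 0.68 ± 0.14 (adjusted p = 0.000175).

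The counts moved with these array facts. There were 3540 genes with the Gapdh gap as a covariate (1620 higher and 1920 lower), 4041 with the 2 late tumours whose gap was at most 2 (1870 and 2171), 4305 with the spike-in set as a block (2758 and 1547) and 2338 within set 3, which holds 2 late tumours (1579 and 759). Dusp6 was at -1.63 (adjusted p = 0.00043) in the low-gap tumours and -1.18 (adjusted p = 0.0038) with the block. Mbp was at 4.09 (adjusted p = 0.015) and 4.83 (adjusted p = 0.0024), and Scn7a at 3.82 and 4.75. For the peripheral nerve list the camera median fell to 0.46 with the gap as a covariate (adjusted p = 0.10). Within set 2 the 8 late tumours lay below the 6 of day 1 in the MAPK activity score (-0.70, exact p = 0.000333, the smallest of 3003 splits). Those late tumours have numbers starting with 3 and those of day 1 numbers starting with 1. Most of those late tumours also have a Gapdh gap over 2, against at most 1.07 at day 1.

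**Figure D3:**
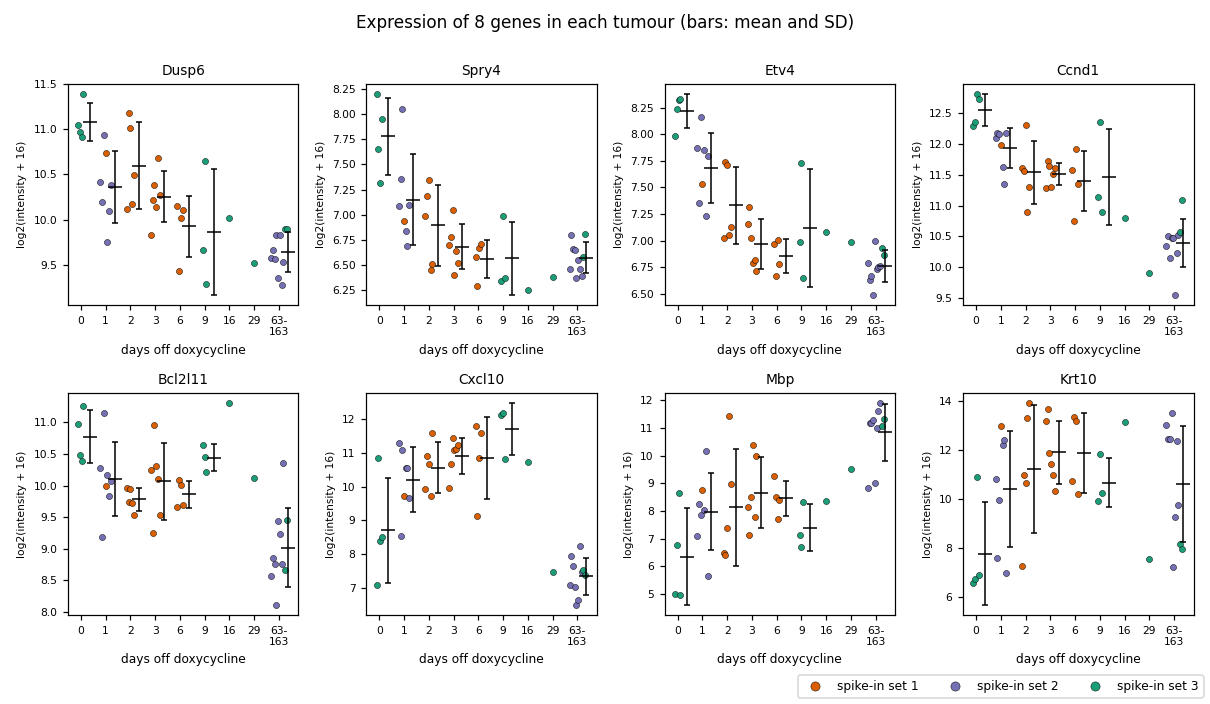
Log2 intensity of 8 genes in each tumour by days off doxycycline, with group means and SD. Dusp6 went from 11.08 at day 0 to 9.64 in the late tumours, Cxcl10 from 11.71 at day 9 to 7.34, and Mbp from 6.36 at day 0 to 10.84.

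The last comparison set the late tumours against the mean of days 6 and 9 to ask what changed later. Interferon-induced chemokine genes Cxcl10 and Cxcl9 fell by a log2 change of -3.94 ± 0.42 (SE, adjusted p = 7.3e-08) and -3.66 ± 0.67, and the interferon regulator Irf7 by one of -3.31 ± 0.35 (adjusted p = 5.46e-08). Complement and Fc receptor genes of macrophages, C1qb and Fcgr1, were at -1.88 ± 0.27 and -2.48 ± 0.30. Cytotoxic cell genes Ccl5 and Gzmb were at -2.82 ± 0.43 and -2.24 ± 0.44, and the immunoproteasome gene Psmb8 at -1.74 ± 0.27. Growth factor gene Fgf5 rose by 3.75 ± 0.43 (adjusted p = 3.74e-07), Cyp2f2 by 3.26 ± 0.37 and the methyltransferase gene Inmt by 3.91 ± 0.64.

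All 30 interferon genes fell, and the score was lower by an exact test of 19448 splits (-1.93 ± 0.19, adjusted p = 0.000874; camera adjusted p = 0.10 with an estimated correlation). MHC class I genes were lower in 13 of 14 (score -1.03 ± 0.13), MHC class II genes in 7 of 8 (-1.19 ± 0.34) and macrophage genes in 16 of 30, 21 over the list alone (-0.94 ± 0.18, adjusted exact p = 0.00175). T and NK cell genes were lower in 13 of 26 and higher in 1 (-0.80 ± 0.20, adjusted exact p = 0.00787). Mitosis genes were lower in 19 of 32, 21 over the list alone (camera median -0.59, adjusted p = 6.6e-08; adjusted p = 0.66 with an estimated correlation), a call lost without the tumours of high Gapdh gap (median -0.16, adjusted p = 0.66). Peripheral nerve genes were higher in 7 of 10, 8 over the list alone (camera median 0.55, adjusted p = 0.0083; adjusted p = 0.37 with an estimated correlation), with a score difference of 0.86 ± 0.14 (adjusted exact p = 0.00175). Without the tumours of high Gapdh gap the camera call of that list ended (median 0.05, adjusted p = 0.39), and so did the calls of Mbp (2.76, adjusted p = 0.12), Scn7a (1.83, adjusted p = 0.06), Cnp (0.72, adjusted p = 0.24) and Pmp22 (0.02, adjusted p = 0.98). The score differences there were 0.56 for nerve, -1.83 for interferon response, -1.23 for MHC class I, -1.31 for MHC class II, -1.03 for T and NK cells and -0.67 for macrophages, none called with 2 late tumours. The MAPK activity score difference did not pass the exact test (-0.19 ± 0.14, p = 0.146), while Ccnd1 fell by 1.04 ± 0.20 and Spry2 rose by 0.55 ± 0.15. Spry2 was at 0.24 (adjusted p = 0.55) without the high-gap tumours, and Ccnd1 at -1.07 (adjusted p = 0.023) there but at -0.85 (adjusted p = 0.055) with the spike-in block.

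Limma called 2553 genes higher and 1975 lower, and 2847 in all without day 9 replicate 2. It called 2663 higher and 1796 lower against day 6 alone, 506 and 592 against day 9 alone, 1015 and 979 with the spike-in block, 950 and 1043 without the tumours of high Gapdh gap and 273 and 478 with the gap as a covariate, so the excess of higher genes held in some settings and not in others. Cxcl10 was at -4.52 (adjusted p = 0.00052) without the high-gap tumours and -4.19 (adjusted p = 0.00046) with the block. Within set 3, 2 late and 3 day 9 tumours differed by -2.13 in the interferon score, where the exact p of 0.1 is the smallest possible, and limma called 36 genes between those tumours.

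**Figure D4:**
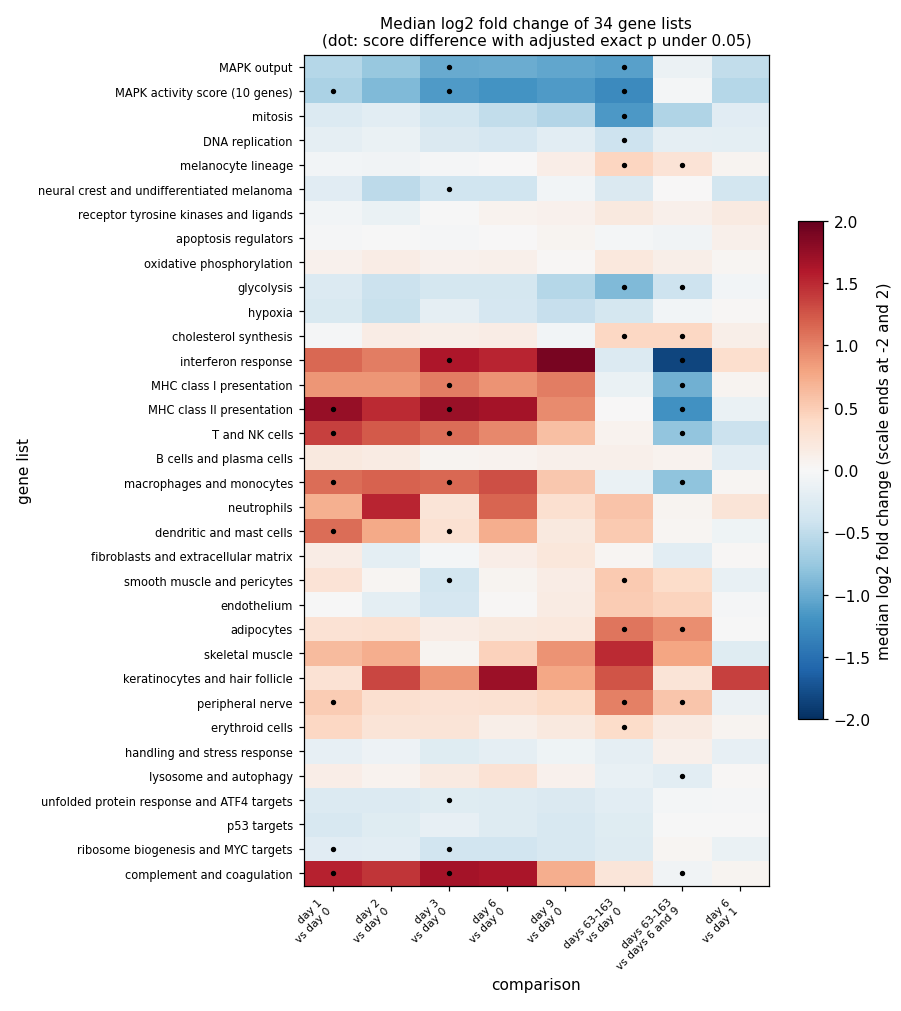
Median log2 fold change of each gene list in each comparison, with a dot where the list score differed by the exact permutation test at an adjusted p under 0.05. Interferon response ran from 1.90 at day 9 against day 0 to -1.84 in the late tumours against days 6 and 9.

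Early and late changes were compared across genes. Of the 273 genes lower at day 9, 266 were also lower in the late tumours, and of the 380 higher, 278 were also higher. Both calls use the same day 0 tumours, which alone raises such an overlap. The fold changes of days 6 and 9 and those of the late tumours correlated across genes with r = 0.758, but genes are not independent and both share the day 0 tumours. Simulated groups with no change and the same controls gave a mean r of 0.670 and a covariance of 0.0365, against 0.251 observed. That simulation had independent noise and no effect of spike-in set, number range or RNA quality. An offset of the day 0 arrays could therefore also raise the covariance above the simulated one. Splitting the day 0 tumours between both sides gave a mean r of 0.614 over 6 splits and covariances from 0.2025 to 0.2488. Those sides share no control, so the r of 0.614 is not to be set against 0.670. Slc9a2, Spred3 and Dusp5 were among the genes lower at day 9.

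Across the 34 lists and 8 comparisons, camera called 109 list tests and 3 of them held with an estimated correlation, while 44 list scores passed the exact test. Of those 3, 2 were the overlapping MAPK lists at day 9. Without day 0 replicate 4 or 3, 27 or 28 scores passed in all.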

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

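The tests of melanoma cell content, nerve pieces and macrophage content and the comparisons within spike-in set 2 and among 3-digit tumour numbers were chosen after the values they bear on had been seen, as were the spike-in sets and the gap limit themselves.

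Of 144 groups of scores or array measures, 10 held a tumour far from the rest, where chance gives about 1 in 20. They were cholesterol synthesis in day 3 replicate 2 (score 8.98), MHC class I in day 6 replicate 2 (10.71), adipocytes (7.75) and skeletal muscle (7.96) in day 1 replicate 2, ribosome biogenesis (9.80) and fibroblasts (10.14) in late replicate 9, neutrophils in day 1 replicate 6 (9.35) and day 2 replicate 1 (10.73), the unfolded protein response in day 2 replicate 2 (9.13) and the Gapdh gap in day 3 replicate 6 (0.44). In the late tumours 12 list scores differed from those of days 6 and 9, and hence in their change from day 0. Higher were the melanocyte lineage (0.32), cholesterol synthesis (0.44), adipocytes (0.74) and peripheral nerve (0.86). Lower were interferon response (-1.93), MHC class I (-1.03), MHC class II (-1.19), macrophages (-0.94), T and NK cells (-0.80), complement (-0.56), glycolysis (-0.41) and lysosome genes (-0.30). The glycolysis call had an adjusted exact p of 0.0444 and ended (0.0512 to 0.103) without any 1 of 11 tumours, namely day 6 replicates 1, 3 and 4, day 9 replicate 2 and late replicates 2, 3, 5, 6, 7, 8 and 10. Melanocyte and adipocyte scores turned to -0.05 and -0.02 without the tumours whose Gapdh gap exceeded 2. For cholesterol synthesis, late replicates 5 and 8, the late tumours of low gap, scored 8.45 and 8.63, within the 8.28 to 8.81 of day 6. In data outside the comparisons, the day 16 tumour had an interferon score of 10.09 and a nerve score of 8.44, the day 29 tumour had a nerve score of 8.53, all above day 0, and 9 late tumours had a Gapdh gap above the highest of day 0.

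Other splits of the same tumours into groups of the same sizes gave fewer genes in 7 comparisons, which argues against chance as their cause, though several splits called many genes. For days 1, 2, 3 and 6 the real split against day 0 also follows spike-in set and number range. There the splits cannot tell withdrawal from batch. The real counts and the highest of the other splits were 1979 and 1330 at day 1, 2161 and 1069 at day 2, 3057 and 919 at day 3, 6647 and 3624 for the late tumours against day 0, and 4528 and 2041 against days 6 and 9, with 1 of 100 splits, the real one, as large in each. At day 6 (1747 and 439) and day 9 (653 and 375) it was 1 of 35, the smallest share possible. The day 9 count was 36 without day 9 replicate 3, so its split says less. For day 6 against day 1, 2 of 100 splits gave as many genes, the other one 652 against 598, still under the share set in advance.

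MAPK activity genes were lower in the late tumours than at day 0. Degraded RNA as the whole cause is argued against by a score difference of -1.33 ± 0.19 (SE) with the Gapdh gap as a covariate, and a labelling or hybridization batch by -0.96 ± 0.21 with the spike-in set as a block, which rests on 2 late tumours, both of gap over 2. Whether fewer melanoma cells could explain it cannot be told apart from lower expression per cell. The 7 abundant melanocyte lineage genes had a median change of -0.20 with an SD of 1.13, too wide to decide. They ran from -1.64 for Pax3 to 1.94 for Cdh19. Cdh19 is also a Schwann lineage gene, so the set does not gauge melanoma cells alone. Within set 3 the exact p was 0.0667, the smallest possible. No late tumour matched day 0 in both spike-in set and low gap, so degraded RNA and batch acting together were not tested. Withdrawal of the BRAF transgene is the difference that the design names, and it stays open beside cell content and beside those 2 together.

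Interferon response genes were lower in the late tumours than at days 6 and 9. Spike-in set 2 holds no tumour of day 6 or 9, so day 1 stood in for them. Within that set the late tumours differed from day 1 by -1.51 (exact p = 0.000333, the smallest of 3003 splits), which argues against spike-in set as the whole cause of the difference from day 1. Number range and Gapdh gap still differed between those late tumours and day 1. Among tumours with 3-digit numbers, 2 late ones (8.05 and 8.06) lay below 3 of day 9 (9.85 to 10.37) by a difference of -2.13, which argues against number range as the whole cause, though the exact p of 0.1 is the smallest possible. These are the same tumours as in the comparison within set 3, and both late ones have a Gapdh gap over 2. With the Gapdh gap as a covariate the difference was -2.02 ± 0.34, which argues against degraded RNA. The interferon score fell more than the macrophage score (-0.99, exact p = 0.000977). That cannot decide on fewer macrophages, as only part of the macrophage list fell and its members C1qb and Fcgr1 fell about as much as the interferon score or more. Other immune cells were not tested. A hypothesis, untested here, is that interferon signalling may rise for some days after BRAF is switched off and then end, which these genes in tumours of days 0, 6, 9 and 63, with and without an interferon receptor block, would test.

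Peripheral nerve genes were higher in the late tumours than at day 0. The score difference was 1.07 ± 0.21 with the gap as a covariate and 1.71 ± 0.26 with the spike-in block, again from 2 late tumours of gap over 2, which argues against degraded RNA or batch, each alone, as the whole cause. No late tumour matched day 0 in both spike-in set and low gap, so the 2 together stay open for this difference. Degraded RNA could still add to it, as the camera call ended with the covariate (median 0.46, adjusted p = 0.10, from 1.01 and 0.015; adjusted p = 0.57 with an estimated correlation), and the 2 late tumours of low gap differed from day 0 by 1.08 without passing (exact p = 0.133, smallest possible 0.0667). Those 2 tumours also had the lowest adipocyte scores of the late tumours (7.07 and 7.19). A change with the gap therefore cannot be told apart from a difference in tissue content. Pieces of nerve in the late tumours and a Schwann-like state of the tumour cells cannot be told apart. The members other than Mbp had a median change of 0.85 with an SD of 1.31, but only Scn7a was abundant enough late and low enough at day 0 to serve, where 3 were required, and it rose nearly as much (4.13) as Mbp (4.48).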

How the results depend on the processing

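Tests of the Gapdh gap, the spike-in sets, unnormalised arrays, no pseudocount and day 2 in place of day 1 were chosen after the data had been seen. Beyond single tumours left out, 5094 gene results, 1006 list tests and 644 scores kept direction and side of the threshold, and 780, 175 and 36 lost their call. The cause was not tested unless stated. Without signal over background or detection calls, a low gene cannot be told from an absent one.

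With every probe set tested, which adds tests, counts rose to 3432 at day 2, 4705 at day 3, 3402 at day 6, 1115 at day 9 and 2086 for day 6 against day 1. Array weights gave 3739 at day 1, 3971 at day 6, 7133 for late against days 6 and 9 and 3200 for day 6 against day 1. Changes of at least 2-fold, fewer by construction, numbered 513, 501, 643, 518, 299, 1597, 594 and 34 in the order of days 1, 2, 3, 6, 9 and late against day 0, late against days 6 and 9, and day 6 against day 1.

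Day 9 gave 0 genes in limma with only the compared groups, with number range as a block or with 3-digit tumour numbers alone (3105 at an unadjusted p under 0.05 in the full fit). It gave 24 without its 1 tumour and the 8 late tumours of high gap. Late against day 0 gave 0 with 3-digit numbers (Lyz2 at -0.14), 3438 with 4-digit numbers starting with 3, 3540 with the gap as a covariate, 4041 without high gaps, 4305 with the spike-in block and 2338 within set 3. Late against days 6 and 9 gave 1098 against day 9 alone, 751 with the gap as a covariate, 1993 without high gaps and 1994 with the block, and within set 3, which holds no day 6 tumour, 36 against day 9. Day 6 against day 1 gave 14 with a slope per day, and 0 with the spike-in block, within set 1 or against day 2, the block and set 1 leaving 1 tumour of day 1. The spike-in block left 79, 134 and 70 genes at days 2, 3 and 6.

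Some directions reversed. The mean of probe sets put Braf at -0.021 in the late tumours. The block put Krt10 (-2.07), Cad (0.52), Braf (-0.11) and Pdgfrb (0.22) at day 3, Sox10 (0.13) at day 6, and Lag3 (0.25, also within set 1) in day 6 against day 1. It also reversed the list tests of ribosome biogenesis (0.32), neutrophils (0.25, by camera's direction) and fibroblasts (-0.28) at day 1, keratinocytes at days 2 (-0.93), 3 (-1.17) and 6 (-0.96), and fibroblasts at days 3 (-0.46) and 6 (-0.40). In day 6 against day 1 it reversed MHC class II (1.44), T and NK cells (0.55), dendritic and mast cells (0.56), keratinocytes (-0.16) and the unfolded protein response (-0.19). Day 2 for day 1 reversed Net1 (-0.063), Dcun1d1 (-0.16), Sox10 (0.017) and Ngfr (0.0052). Without high gaps Mb was at -0.074 (late against day 0), and against days 6 and 9 Hspa1a was at -0.092, skeletal muscle at -0.23 (-0.58 with the gap as a covariate), ribosome biogenesis at -0.23, neutrophils at 1.18 (0.65 with the gap as a covariate), fibroblasts at 0.12, keratinocytes at -1.63, and the melanocyte and adipocyte scores at -0.054 and -0.022.

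Estimated correlation left 3 of 109 list tests. Without high gaps all 23 score calls of late tumours ended, where 2 late tumours allow none against day 0, and against days 6 and 9 only if most lists reach the smallest p. The other 21 of the 44, at days 1 and 3, lost no tumour. The shared covariance without high gaps was 0.170 against 0.251. Splits of the day 0 tumours gave 0.2202, 0.2053, 0.2107 and 0.2025.

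Leaving out 1 tumour gave 889 (day 0 replicate 4) to 2456 genes at day 1, 1178 to 2080 at day 2, 1633 to 3133 at day 3, 832 to 1716 at day 6, 36 to 1236 at day 9, 5681 to 6920 for late against day 0, 2847 to 5237 against days 6 and 9, 254 to 1165 for day 6 against day 1, 102 to 114 list tests and 27 to 46 scores. The lowest counts at days 1, 2, 3 and 6 and of scores were without day 0 replicate 4, and at day 9 without day 9 replicate 3.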

Other observations

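Everything in this part was read after the results had been seen, with no further test of a hypothesis. Some single genes of other kinds differed between the late tumours and day 0. The EGFR ligand genes Hbegf and Ereg were at -2.90 ± 0.32 (SE, limma adjusted p = 3.01e-08) and -2.70 ± 0.44, while Gas6, the ligand of the AXL family, rose by 1.98 ± 0.37. Without the tumours whose Gapdh gap exceeded 2, Gas6 was at 1.31 (limma adjusted p = 0.043), Hbegf at -2.15 and Ereg at -3.31. Fbln2, a basement membrane gene, fell by 2.45 ± 0.24 (adjusted p = 7.42e-09), and Cspg4, a proteoglycan gene of melanoma cells and pericytes, fell by 2.51 ± 0.28. The list of fibroblasts and matrix had 11 of 32 members higher and 8 lower, the same over the list alone. Among p53 targets Fas and Sesn1 rose by 1.02 ± 0.14 and 1.55 ± 0.21, and Sesn2 and Gtse1 were at -1.69 ± 0.26 and -0.89 ± 0.13. Sesn1 was at 0.98 and Sesn2 at -0.87 with the Gapdh gap as a covariate, and Sesn2 was at -0.78 (adjusted p = 0.046) without the tumours whose gap exceeded 2. The cholesterol synthesis genes Msmo1 and Idi1 rose by 1.75 ± 0.33 and 1.55 ± 0.29, and the hypoxia gene P4ha1 fell by 1.96 ± 0.25. Msmo1 lost its call with the spike-in set as a block (0.92, adjusted p = 0.13). Mitochondrial Ndufb9 rose by 0.78 ± 0.11 and polyamine gene Odc1 fell by 1.97 ± 0.28. Lymphatic endothelial Lyve1 rose by 2.81 ± 0.44, and by 1.80 (adjusted p = 0.026) with the block.

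At day 3 the list of the unfolded protein response and ATF4 targets had 5 of 22 members lower and 1 higher, 7 and 1 over the list alone. Its score differed by -0.28 ± 0.11 (adjusted exact p = 0.0162), while camera did not call it (adjusted p = 0.055) and the score call ended with arrays centred on their medians (adjusted exact p = 0.12). Among its members Mthfd2 was at -0.94 ± 0.19 (SE, adjusted p = 0.000599) and Asns at -1.16 ± 0.27, which were at -0.48 (adjusted p = 0.63) and -1.05 (adjusted p = 0.44) with the spike-in set as a block. Ribosome biogenesis genes were lower in 9 of 25, 10 over the list alone, and their score by a difference of -0.42 ± 0.09 (adjusted exact p = 0.0162). Their camera call (median -0.38, adjusted p = 0.0002; adjusted p = 0.51 with an estimated correlation) ended with the spike-in block (median 0.06, adjusted p = 0.60).

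Late tumours varied in the scores of other tissues. Skeletal muscle scores ran from 5.43 to 9.33 (SD 1.44, n = 10) and keratinocyte scores from 5.81 to 10.66, against 7.60 to 8.14 (SD 0.18) for the MAPK activity score and 7.55 to 8.49 (SD 0.26) for interferon response. Mitosis scores ran from 6.17 to 8.03 (SD 0.62) there and from 7.87 to 8.78 at day 0.

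The single day 16 and day 29 tumours had MAPK activity scores of 7.87 and 7.59, below the lowest day 0 tumour at 8.87. Their interferon scores were 10.09 and 7.89. Ccnd1 was at 10.80 and 9.91, and Mbp at 8.38 and 9.53.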
